A study of Mus musculus with 11 samples.

How the data were processed

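Poly(A) RNA sequencing libraries of mouse BAT and liver were grouped by tissue and virus from the sample titles: 2 BAT control, 3 BAT Cre, 3 liver control and 3 liver Cre libraries. Library numbers are unique across groups, and whether BAT and liver came from the same mice is not given in the labels. The numbers run in the same order in both tissues, and Y-linked genes were highest in the first library of each, so shared mice are not excluded. No paired analysis was made, because the labels tie no BAT library to a liver library. The protocol describes both directional and non-directional library preparation and does not say which was used, so genes that overlap on opposite strands cannot be told apart.

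The deposited tables hold 1 score per gene and library, for 2500 genes in each tissue. From the values, the liver scores are row z-scores: all 2500 rows sum to 0 and their squares sum to 6, within 1e-06. In BAT the squares of the 5 values sum to 6 in all 2500 rows once minus their sum is added as 1 more value, so the scaling ran over 6 libraries, and the further library is not analysed here. The submitters' processing notes name TopHat 1.3.3, DESeq2 1.20.0 and the builds mm9, mm10 and GRCm38 without saying which step or file each belongs to. How the 2500 genes were chosen, and whether values were log transformed before scaling, is not given in the sources used here. Names given to the deposited tables mention genes lower in Cre for BAT and higher in Cre for liver, but both tables hold genes of both directions. If the genes were chosen for differing between libraries, the counts below are not independent evidence of a difference. A z-score has a maximum of 2.24 with 6 libraries, keeps no level, depth or fold, and makes 1 extreme library push the remaining ones together. In 331 BAT and 61 liver genes at least 2 libraries were tied at the lowest value.

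The test fixed before the data were examined was limma with variance moderation on log2 normalized counts, which the z-scores do not allow. It was replaced by limma's gene-wise linear model (limma 3.58.1, R 4.3.3) on z-scores without moderation, two-sided, with Benjamini-Hochberg adjustment over the 2500 genes and a threshold of 0.05, because scaling gives every gene the same total variance. Moderation was kept as an alternative. Genes without spread within groups (residual SD under 1e-06) were not tested, a rule added after libraries left out in turn gave p-values of 0 for tied genes. On simulated z-scored tables with 200 of 2500 genes changed, the gene-wise model recovered 0.1%, 3.225% and 93.9% of genes shifted by 3, 6 and 12 within-group SD in the BAT layout, and 0.275%, 72% and 99.92% in the liver layout. The moderated model recovered 0% in each. Shifts of 3 SD were thus rarely detectable in either layout. Genes whose Cre libraries all lay on 1 side of all controls are called non-overlapping.

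The 50 gene lists (33 pathways and 17 cell type marker lists) were fixed before the data were examined. Competitive set tests had been planned only for tables of at least 8000 genes and were not run. For each list the members in the table were counted, members past the threshold were counted over all genes and adjusted over the list alone, and for lists of at least 3 members the mean z-score per library was compared by an exact two-sided permutation test, whose smallest possible p is 0.1 in either tissue. Those tests of list means were added after the tables were seen. They covered 23 lists in BAT and 35 in liver, with smallest Benjamini-Hochberg values of 0.511 and 0.583. No list member passed over all genes, and 4 BAT and 2 liver entries passed adjusted over the list alone. The difference between tissues was tested in limma over the 4 groups for the 526 shared genes, although the tissues were scaled separately. That test and the numbers of genes that independent lists would share take the tissues as coming from separate mice.

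Named genes followed a rule fixed beforehand, except for its filter on mean normalized count, which z-scores do not allow. Some named genes may therefore have low counts. As fewer than 5 genes passed in each direction, the 5 with the smallest unadjusted p per direction were named among non-overlapping genes whose symbols are not predicted or clone names. For each list up to 2 members were named. The rule ranked them by mean count, which z-scores do not keep, so the earliest members in list order were taken, and any further gene named was chosen after its values were seen. For the tissue difference the 5 smallest p-values per direction were taken among genes non-overlapping in both tissues. Positions are from the GENCODE mouse release 21 annotation of GRCm38, in which 2427 BAT and 2415 liver symbols matched a single gene. Further marker sets (lymph node, lung, sarcomere, brown fat and others) were written after the tables had been seen. Summaries and figures used Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

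Alternatives were leaving out each library, array weights, moderation, protein-coding genes only, and leaving out pairs of libraries that stood apart. The default array weights did not converge in liver, so the gene-by-gene method was used in both tissues, a change made after that was seen.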

Results

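RNA was sequenced from brown adipose tissue (BAT), the fat depot that produces heat, and from liver of mice carrying floxed alleles of Adcyap1r1, the gene of the PACAP receptor PAC1. The mice had received an adeno-associated virus (AAV) in the preBötzinger complex, a brainstem region that generates the breathing rhythm. The virus encoded either GFP (control) or Cre recombinase (Cre), which excises floxed sequence, and the mice underwent a procedure the labels call SEFL, an abbreviation they do not expand. BAT was represented by 2 control libraries (1 and 2) and 3 Cre libraries (4, 5 and 6), and liver by 3 control libraries (7, 8 and 9) and 3 Cre libraries (10, 11 and 12). Each tissue came as a table of 2500 genes in z-scores, in which every gene is centred and divided by its own SD over 6 libraries, so values state where a library lies for a gene and not how much RNA there was. Sequencing depth is unknown, and no fold change can be given. The labels do not say that the libraries came from separate animals, so p-values measure only the spread between these libraries. Adcyap1r1 was in neither table, and since the virus was given in the brain its level in BAT or liver would not check the deletion.

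The first comparison asked how BAT of Cre mice differed from BAT of controls. All 14 of 14 skeletal muscle genes were in the table, and for all 14 the 3 Cre libraries lay below both controls. The further library included in the BAT scaling is not analysed here, so this separation holds for the 5 analysed libraries only. Acta1, the actin of skeletal muscle, had a z-score of -0.57 ± 1.15 (SD, n = 3) in Cre and 1.05 ± 0.03 (SD, n = 2) in control, and Ckm, the muscle creatine kinase, -0.53 ± 1.23 and 0.99 ± 0.11. The list mean was -1.88 in Cre 4, 0.11 in Cre 5 and 0.07 in Cre 6, against 1.09 and 1.02 in controls 1 and 2. Cre 4 also stood apart for 5 lung epithelium genes, chosen after the tables were seen, with a mean of 2.04. Cre minus control of the list was -1.62 with all libraries and -0.96 without Cre 4. The exact two-sided permutation test over all 10 arrangements of the libraries gave p = 0.2.

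The 3 heat shock genes in the table lay lower in Cre, with every Cre library below both controls. Hspa1a, an inducible HSP70 chaperone, had -0.75 ± 0.57 (SD, n = 3) in Cre and 1.28 ± 0.52 (SD, n = 2) in control, and its near-identical neighbour Hspa1b, whose reads may be shared with it, -0.81 ± 0.36 and 1.26 ± 0.77. None of the 3 passed over all genes, where the smallest limma adjusted p was 0.40. The 2 that passed adjusted over the list alone were Hspa1a and Hspa1b, which may be a single signal because of those shared reads. Of 8 glucocorticoid-induced genes, 6 had a lower Cre mean and 3 had non-overlapping groups, shares near those over all 2500 BAT genes (82.5% and 33.0%). Among the 3 was Fkbp5, a co-chaperone of the glucocorticoid receptor, at -0.84 ± 0.90 (SD, n = 3) in Cre and 0.87 ± 0.38 (SD, n = 2) in control. The lipogenic desaturase genes Scd1 and Scd2 had Cre means of -0.50 and -0.32 against control means of 1.2 and 1.14. The lipogenesis list, with 3 genes in the table, differed by -1.1 with all libraries, at an exact permutation p of 0.3. Its difference was -1.55 without control 1 and -0.65 without control 2. Bdh1, an enzyme of ketone body metabolism, had a Cre mean of -0.55 and a control mean of 1.36, while Acot1, an acyl-CoA thioesterase, had 0.51 and -1.29. These 2 genes were the only members of the PPARalpha and ketogenesis list in the table, and both passed adjusted over the list alone and not over all genes.

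Of 24 cytosolic ribosome genes 23 had a lower Cre mean, 9 of them with non-overlapping groups, and 22 were highest in control 1. Their list mean was 1.41 in control 1 and -0.14 in control 2, and Cre minus control was -1.18 with all libraries and -0.41 without control 1. Many of these genes have processed pseudogenes with near-identical sequence, so their reads are uncertain. Among 6 nuclear-encoded respiratory chain genes 4 had a lower Cre mean, a smaller share than over all genes. Cox6a2, 1 of the 4 and the subunit isoform of heart and skeletal muscle, had -0.61 ± 1.03 (SD, n = 3) in Cre and 1.13 ± 0.03 (SD, n = 2) in control. It followed the skeletal muscle list, with -1.8 in Cre 4, and its difference was -1.74 with all libraries and -1.15 without Cre 4. The heat shock, glucocorticoid, cytosolic ribosome and respiratory chain lists were the 4 of 23 BAT lists at an exact permutation p of 0.1, the smallest that 3 libraries against 2 can give, and the adjusted value over the 23 lists was 0.511.

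Of 26 genes of the thermogenic program 4 were in the BAT table, and Ucp1 was not among them. Dio2, which activates thyroid hormone, had a Cre mean of -0.29 and control values of -1.54 and 1.39. Kcnk3, a potassium channel gene, had a Cre mean of 0.42 and a control mean of -1.02. It had 1.57 in Cre 5, but -0.53 in both Cre 6 and control 2. The list mean differed by 0.05 between Cre and control, and by -0.70 without control 1 and 0.81 without control 2. No member of the fatty acid oxidation, TCA cycle, branched-chain amino acid, mitochondrial ribosome or endothelial lists was in the table.

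Immune genes were apart in a single library. The mean of 12 T and NK cell genes was 2.16 in control 1, -0.60 in control 2, and -0.49, -0.19 and -0.55 in Cre 4, 5 and 6. Cd3e, a chain of the T cell receptor complex, had 2.21 in control 1 and -0.74 in control 2. The 25 interferon-stimulated genes averaged 2.03 in control 1 and -0.65 in control 2, with Cre libraries between -0.62 and -0.12, and Ifit1 followed them with 2.19 and -0.40 in the controls. The 9 macrophage genes averaged 1.93 and -0.61 in controls 1 and 2, and the 12 proliferation genes 2.10 and -0.30. Cre minus control of the T and NK list was -1.19 with all libraries and 0.19 without control 1. The exact permutation p of these 4 lists lay between 0.2 and 0.4. Extracellular matrix genes were highest in Cre 5 with a mean of 1.66, where the 4 mitochondrially encoded genes had a mean of -2.16. The 8 hepatocyte genes averaged 1.66 in Cre 6.

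**Figure D1:**
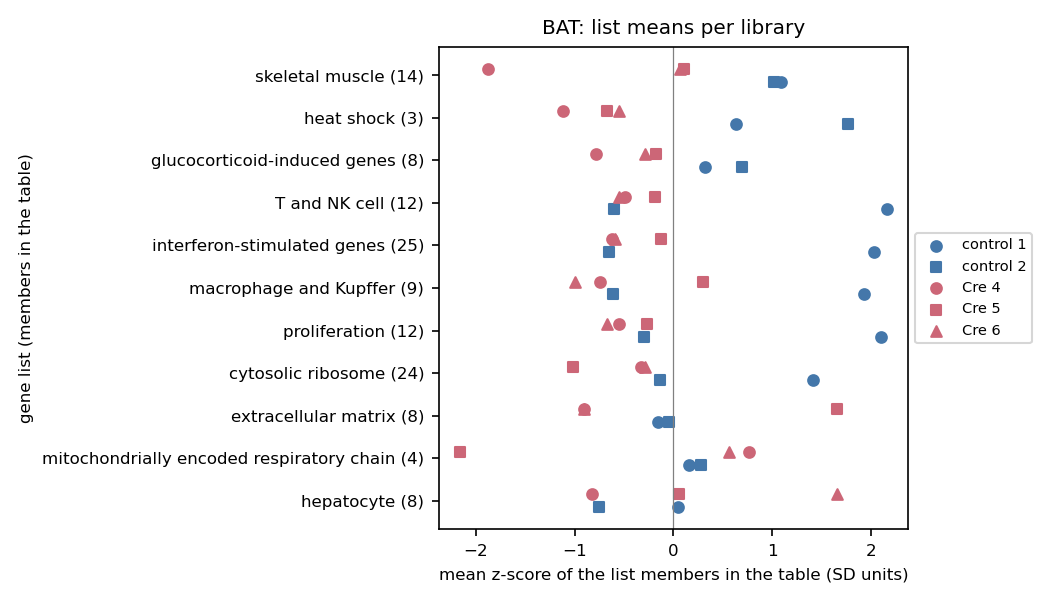
Mean z-score (SD units, horizontal axis) of the members of 11 gene lists in each BAT library, with the number of members in the table in parentheses. Blue symbols are the 2 control libraries and red symbols the 3 Cre libraries. Control 1 lies at 2.16 for T and NK cell genes while control 2 lies at -0.60 among the Cre libraries, whereas both controls lie above all Cre libraries for skeletal muscle.

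No BAT gene passed an adjusted p of 0.05 in limma's gene-wise linear model, where the smallest adjusted p was 0.363. None passed with variance moderation either, but that model recovered 0% of changed genes in the simulations, so this decides nothing. At an unadjusted p under 0.05 there were 23 genes higher and 262 lower in Cre, 285 in all, and 17 and 209 with moderation. A share of 0.05 of all genes is expected by chance, and the highest of the other splits gave 142. Groups did not overlap for 826 genes (109 higher, 717 lower), or 33.0% where chance gives 20%. A split that set control 1 and Cre 5 apart from the rest gave 813, so an excess near this size is not particular to Cre against control. The genes with the smallest unadjusted p, none past the threshold, were Efcab6, Dok7, Lrrc14b, Colq and Pdlim5 among those lower in Cre. Dok7 and Colq encode proteins of the neuromuscular junction. Efcab6 (chromosome 15, 83866712 to 84065379 in the GRCm38 annotation) differed by -2.16 with a standard error of 0.088, and Dok7 (chromosome 5, 35056766 to 35087839) by -2.18 with a standard error of 0.15. Those higher in Cre were Aspg, Sh3tc2, S1pr5, Mup18 and Wscd1. Aspg (chromosome 12, 112106679 to 112127559), which encodes an asparaginase, differed by 2.20 with a standard error of 0.24. Mup18 belongs to a family of near-identical genes, so its reads are uncertain.

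Control 1 decided the balance of the BAT comparison. It was the highest library for 1767 of the 2500 genes, or 70.7% where chance gives 20%, and control 2 for 218. Control 1 was also the single BAT library with high Y-linked genes. If these mark a male animal, what control 1 alone carried cannot be assigned to virus rather than sex. The Cre mean was the lower one for 82.5% of genes with all libraries and for 49.4% without control 1, and 49.6% of genes were then non-overlapping, where chance gives 50% for 3 libraries against 1. Without control 2, which leaves control 1 alone and assumes that it varies like the Cre libraries, 433 genes passed the adjusted threshold and 86.5% were non-overlapping, where chance also gives 50%.

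**Figure D2:**
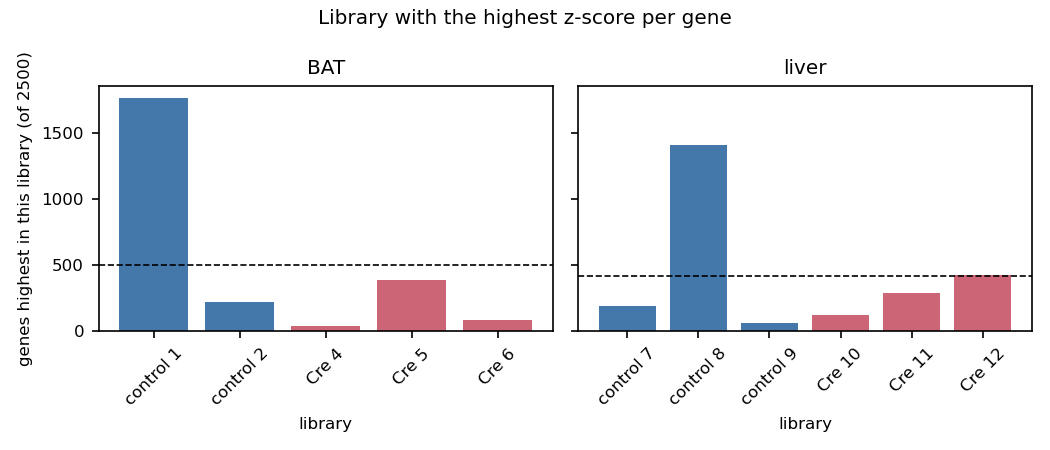
Number of genes (vertical axis, of 2500 per tissue) whose highest z-score was in each library, for BAT on the left and liver on the right. Blue bars are control and red bars Cre libraries, and the dashed line is the number with equal shares. Control 1 holds 1767 genes in BAT and control 8 holds 1409 in liver.

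The second comparison asked how the liver of Cre mice differed from that of controls. All 8 genes of amino acid breakdown and the urea cycle in the table had a higher Cre mean, and for 6 of them every Cre library lay above every control. Cps1, which catalyses the entry step of the urea cycle, had 0.84 ± 0.25 (SD, n = 3) in Cre and -0.84 ± 0.91 (SD, n = 3) in control, and Ass1, an enzyme of the same cycle, 0.80 ± 0.58 and -0.80 ± 0.87. The list mean was 0.51, 0.58 and 1.06 in Cre 10, 11 and 12 and -0.26, -1.10 and -0.80 in controls 7, 8 and 9, a difference of 1.44 that stayed between 1.24 and 1.67 when any 1 library was left out. The lowest of these, control 8, had -1.84 for hepatocyte genes, a list that includes Cps1. The highest, Cre 12, had 2.09 for adipocyte genes. Its exact permutation p of 0.1 is the smallest that 3 libraries against 3 can give, and over the 35 lists tested the adjusted value was 0.583.

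Of 8 gluconeogenesis and glycogen genes 7 had a higher Cre mean, and 3 had non-overlapping groups. Fbp1 and Pcx, enzymes of gluconeogenesis, had Cre means of 0.75 and 0.70 against control means of -0.75 and -0.70, with -2.0 and -2.10 in control 8. The list mean differed by 0.90, by 0.58 without control 8 and by 0.57 without Cre 12, which was highest for 6 of the 8 genes. The 4 genes of the TCA cycle list in the table were Idh2, Ogdh, Sdha and the pyruvate dehydrogenase kinase gene Pdk4. The 4 of the fatty acid oxidation list were Acads, Hadha, Etfdh and Cpt1b, with 1.76 for Cpt1b in Cre 12. All had a higher Cre mean, with list differences of 1.2 and 0.98. These were 0.75 and 0.72 without Cre 12 and 0.80 and 0.55 without control 8. Both libraries also stood apart for markers of cell types: control 8, at -1.4 and -1.37 in these lists, had -1.84 for hepatocyte genes, and Cre 12, at 1.51 and 1.02, had 2.09 for adipocyte genes. Together with the amino acid, gluconeogenesis and female-biased lists they were the 5 liver lists at an exact permutation p of 0.1. Of the cytosolic ribosome list 2 genes were in the liver table, Rps12 with a Cre mean of 0.91 and Rpl27 with -0.86. Both passed adjusted over the list alone and not over all genes. Rps12 differed by 1.83 and its pseudogene Rps12-ps3 by -1.96, each with non-overlapping groups, so reads of Rps12 are uncertain. All 9 PPARalpha targets had a higher Cre mean, and no member had non-overlapping groups. Cyp4a14, a fatty acid hydroxylase, had -1.83 in control 7 and 0.90 in control 9, within the range of the Cre libraries. Of 18 cholesterol synthesis and uptake genes 17 had a higher Cre mean and 17 were highest in Cre 11, where the list mean was 1.36. Hmgcs1, an early enzyme of the pathway, had 1.60 in Cre 11 and -1.40 in Cre 12. The 14 lipogenesis genes were split, with 9 higher and 5 lower Cre means. Of 5 bile acid genes 3 had a lower and 2 a higher Cre mean, with a list difference of -0.33 that was 0.03 without Cre 12. Irs2, an adaptor of the insulin receptor, had 0.76 ± 0.68 (SD, n = 3) in Cre and -0.76 ± 0.89 (SD, n = 3) in control. Its groups overlapped, with -1.73, -0.58 and 0.02 in controls 7, 8 and 9 and 1.32, 0.01 and 0.96 in Cre 10, 11 and 12.

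Sex-biased liver genes were furthest from the other libraries in control 7, and no member passed the test. All 17 female-biased genes had a higher Cre mean, 8 of them with non-overlapping groups, and all 14 male-biased genes had a lower one, 3 of them with non-overlapping groups. The female-biased list averaged -1.85 in control 7, 0.11 and 0.07 in controls 8 and 9, and 0.74, 0.48 and 0.45 in Cre 10, 11 and 12. Cyp2b9 followed it with -2.21 in control 7 and 0.15 in control 8. The male-biased list averaged 1.89 in control 7 and -0.90 to 0.18 in the other libraries, and Cyp2d9 had 2.05 there. The difference of the female-biased list was 1.11 with all libraries and 0.47 without control 7, and that of the male-biased list -1.11 and -0.45. The exact permutation p was 0.1 for the female-biased and 0.2 for the male-biased list. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, chosen after their values were seen, were highest in control 7 in liver and in control 1 in BAT. Ddx3y had 2.23 in both of these libraries, and Kdm5d had 1.63 in liver control 7 and 1.16 in liver control 8. No Cre library of either tissue exceeded 0.06 for these genes. If high values mark male animals, what liver control 7 and BAT control 1 alone carried cannot be assigned to virus rather than sex.

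Control 8 held the highest value for all 13 mitochondrially encoded genes, with a list mean of 2.01, and for all 9 B and plasma cell and all 5 T and NK cell genes, with means of 1.98 and 1.87. All 13 mitochondrially encoded genes had a lower Cre mean, 7 of them with non-overlapping groups, and the list difference was -1.26 with all libraries and -0.56 without control 8, at an exact permutation p of 0.2. The 4 hepatocyte genes, Cps1 among them, averaged -1.84 there, and Alb, the albumin gene, had -2.15. Cre minus control of this list was 0.81 with all libraries and 0.1 without control 8. Cre 12 held the highest value for all 6 adipocyte genes, with a mean of 2.09, and for 9 of 11 thermogenic genes, with a mean of 1.69. Ucp1, the uncoupling protein of brown fat, had 2.17 in Cre 12 and between -0.65 and 0.05 in the other liver libraries.

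**Figure D3:**
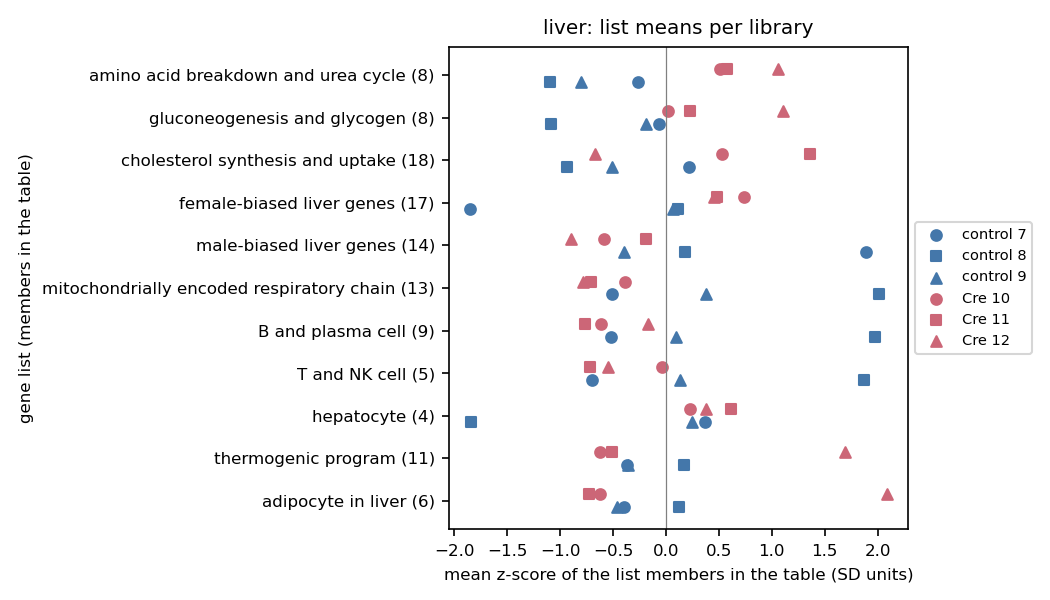
Mean z-score (SD units, horizontal axis) of the members of 11 gene lists in each liver library, with the number of members in the table in parentheses. Blue symbols are the 3 control libraries and red symbols the 3 Cre libraries. For amino acid breakdown and the urea cycle the Cre libraries lie between 0.51 and 1.06, above all controls, while control 7 lies at -1.85 for female-biased genes and Cre 12 at 2.09 for adipocyte genes.

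No liver gene passed the adjusted threshold in limma's gene-wise model, where the smallest adjusted p was 0.13. None passed with moderation either, which recovered 0% of changed genes in the simulations and so decides nothing. At an unadjusted p under 0.05 there were 81 genes higher and 63 lower in Cre, 144 in all, and 66 and 51 with moderation. A share of 0.05 of all genes is expected by chance, and the highest of the other splits gave 119. Groups did not overlap for 565 genes (258 higher, 307 lower), or 22.6% where chance gives 10%. A split that grouped control 7 with Cre 11 and Cre 12 gave 539, so an excess near this size is not particular to Cre against control. The smallest unadjusted p belonged to Lrch4 (chromosome 5, 137629121 to 137641099), which was 0.99 ± 0.11 (SD, n = 3) in Cre and -0.99 ± 0.15 (SD, n = 3) in control and did not pass the threshold. Abtb2, Lrfn3, Pdp2 and Ephb6 came next among genes higher in Cre. Pdp2, a phosphatase that activates pyruvate dehydrogenase, had 0.96 ± 0.26 and -0.96 ± 0.40. Pin4, Rwdd2a, Derl3, Pi15 and Rbmxl2 had the smallest unadjusted p among genes lower in Cre, and Pin4 (chromosome X, 102119447 to 102127669) had -0.95 ± 0.36 in Cre and 0.95 ± 0.39 in control. The Cre mean was the lower one for 60.4% of genes with all libraries and for 44.2% without control 8. With 1 library left out chance gives 20% non-overlapping genes, and the share was 28.7% without control 8, 27.9% without Cre 11 and 47.0% without control 7.

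The third comparison asked whether the Cre difference was the same in both tissues, over the 526 genes in both tables. Srl, a calcium-binding protein gene of the sarcoplasmic reticulum, had a Cre minus control difference of -2.01 in BAT and 1.63 in liver, and Nqo1, a quinone reductase gene, -1.86 and 1.71. Slc25a25, a mitochondrial carrier gene, Dsp and Ppl also lay lower in Cre in BAT and higher in liver, with non-overlapping groups in each tissue. Mettl20, Mup16, Mup14 and Apoc1 lay the opposite way, with Mettl20 at 1.68 in BAT and -1.70 in liver. Srl had its highest liver value in Cre 12 (1.73), where Acta1, with differences of -1.62 in BAT and 0.94 in liver, had 2.23 and 9 further sarcomere genes, chosen after the tables were seen, averaged 1.74. Mup14 and Mup16 had their highest BAT values in Cre 6 (1.46 and 1.42), where 14 further hepatocyte genes averaged 2.10, and Apoc1 in Cre 5 (1.34). For liver, Mup20 of the same family is on the male-biased list, which averaged 1.89 in control 7. Whether the liver differences of Mup14 and Mup16 follow that library was not tested. Ccar1, the next by p with a positive difference and non-overlapping groups in both tissues when predicted genes are left aside, lay lower in Cre in both tissues, with -1.43 and -1.51 and an unadjusted limma p of 0.933 for the difference. No gene passed the limma test of the difference between tissues, where the smallest adjusted p was 0.426. An unadjusted p under 0.05 was reached by 36, of which 8 were more positive and 28 more negative in BAT. A share of 0.05 of the 526 genes is expected by chance.

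Across these 526 genes, which are not independent replicates, the Cre differences of the tissues had a Pearson correlation of 0.11 and a Spearman correlation of 0.08. The Pearson value was -0.09 without BAT control 1, and 1 gene then passed the test of the difference. Groups did not overlap in both tissues for 8 genes lower in both and 1 higher in both, where independent lists would share 13 and 3.1. They did so in opposite directions for 9 genes lower in BAT and higher in liver and 5 the other way, where independent lists would share 12.1 and 3.3.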

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

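All tests of explanations in this part were chosen after the result was seen. In 9 of the genes named for the tissue difference the Cre libraries lay on opposite sides of the controls in the 2 tissues. They were named for non-overlapping groups in both tissues and a small p for the difference, so opposite sides largely follow from that choice. Over the 526 shared genes, 9 lay lower in BAT and higher in liver and 5 the other way. Independent lists would share 12.1 and 3.3. In limma's test of the difference none of the 9 passed, with adjusted p-values from 0.43 to 0.69. The difference, BAT minus liver, was 3.39 for Mettl20, 3.21 for Mup16, 2.94 for Mup14 and 2.77 for Apoc1. It was -3.64 for Srl, -3.57 for Nqo1, -3.52 for Slc25a25, -3.04 for Dsp and -2.93 for Ppl. The gluconeogenesis and glycogen list also lay on opposite sides, with a difference of -2.4 that was not tested. It sets 2 genes in BAT (Ugp2 and Igfbp1) against 8 others in liver, so it does not compare the same genes between tissues.

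Immune genes were highest in BAT control 1. Of the 54 genes of the T and NK cell, macrophage, interferon and inflammatory lists, 53 had their highest value there. The mean of the 54 genes was 2.05 in that library. Control 1 was also the highest library for 70.7% of all BAT genes, with a mean of 1.29 over all genes. Being highest there is thus not particular to immune genes, and a shift of the whole library was not tested as an explanation. An effect of AAV-Cre as the whole cause of the immune pattern is argued against by control 2. Its mean over the 54 genes, -0.64, lay with the Cre libraries and not with control 1. Cre 4, 5 and 6 had -0.60, -0.07 and -0.63. Scaling keeps the order of libraries within each gene, but 1 extreme library makes the gaps among the rest small. The argument also rests on 2 controls that disagree. Lymph node in the dissected tissue stays open, because 4 of 13 lymph node genes were in the table, although Ccl21a, a lymph node chemokine, was -0.95 in control 1. The sex of the animal also stays open, because control 1 was the single BAT library with high Y-linked genes (mean 2.21). In the other tissue this did not recur: liver control 7, with high Y-linked genes, had means of -0.70 for T and NK cell, -1.29 for macrophage and -1.14 for interferon-stimulated genes.

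Sex-biased genes were apart in liver control 7. A male animal behind that library may account for this, since all 4 Y-linked genes were highest there with a mean of 2.02. Control 8 was not uniformly low, with 1.16 for Kdm5d and 0.36 for Uty, and the labels give no sex. An effect of AAV-Cre stays open. The female-biased list differed by 0.47 without control 7, but its sign was fixed beforehand, since the list means of all 3 Cre libraries lay above those of all 3 controls.

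Muscle genes lay lower in BAT Cre. Skeletal muscle in the dissected tissue and an effect of AAV-Cre on muscle genes cannot be told apart. A set of 14 further sarcomere genes ordered the 5 libraries as the fixed list did, with a rank correlation of 1.0, which both explanations predict. The exact permutation p of the fixed list was 0.2, and the amount of muscle was not measured otherwise.

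The count of non-overlapping genes was as large in 1 of the 10 splits of the BAT libraries, the real one, with 826 genes against 813 in the highest other split, which set control 1 and Cre 5 apart from the rest. In liver it was also 1 of 10, with 565 against 539. At an unadjusted limma p under 0.05 the real split had 285 genes in BAT against 142 in the highest other split, and 144 against 119 in liver. Genes past the adjusted threshold numbered 0 in both real splits, which 10 of 10 splits reach by construction, so this count tests nothing. The highest other split had 1 in BAT and 0 in liver. With 10 splits no share under 0.05 can be had.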

How the results depend on the processing

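The count of 0 genes past the adjusted threshold was the same in both tissues with array weights and with protein-coding genes only. In liver it was also 0 without control 8 and Cre 12. It was 0 with moderation too, but that model recovered 0% of changed genes in the simulations, so its count adds nothing. At an unadjusted p under 0.05 limma gave 23 higher and 262 lower genes in BAT, but 11 and 132 with array weights and 35 and 48 without control 1 and Cre 6. In liver it gave 81 and 63, 96 and 81 with array weights, and 86 and 129 without controls 7 and 8. Leaving out each library gave 0 to 433 genes in BAT, the highest without control 2, and 0 to 0 in liver. List members past the threshold ranged from 0 to 33. The tissue difference gave 0 to 1 genes and the correlation -0.09 to 0.21. Over libraries left out in turn, non-overlapping genes relative to chance ranged from 0.99 to 1.73 in BAT and 1.39 to 2.35 in liver, and the percentage of genes with a lower Cre mean from 49.4 to 86.1 and from 44.2 to 63.7. With protein-coding genes only the BAT ratio was 1.9. Chance shares differ between layouts, which bounds the ratio, so ratios with different numbers of libraries are not directly comparable. Pairs of libraries left out were chosen after seeing the data. Without BAT control 1 and Cre 6 the ratio was 0.92 and the percentage 46.3. Without liver control 8 and Cre 12 they were 1.2 and 47.4, and without controls 7 and 8 the ratio was 1.15. The list difference changed sign for 12 of 23 BAT lists and 14 of 35 liver lists when libraries were left out in turn. Of the named genes, 28 of 74 in BAT and 33 of 86 in liver changed sign under at least 1 alternative, and 13 BAT genes passed the threshold without control 2. Alternatives on pseudocounts, low-value filters, TMM or upper-quartile scaling, count models and competitive set tests were not run, since z-scores keep no counts. Depth is unknown, so what it limits cannot be stated.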

Other observations

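The marker sets in this part were chosen after the tables had been seen. Transcripts of other tissues stood out in single libraries. In BAT Cre 6 all 14 of 14 further hepatocyte genes were highest, with a mean of 2.10. In BAT Cre 4 all 5 lung epithelium genes in the table, among them the surfactant genes Sftpc and Sftpb, were highest, with a mean of 2.04. In liver Cre 12, 9 of 10 brown fat genes and 8 of 9 sarcomere genes were highest, with means of 1.89 and 1.74. Epithelial keratin and secretory genes, 11 of 15 in the BAT table, had means from -0.57 to 0.31.

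In liver control 8 all 17 immunoglobulin genes and all 11 further immune genes were highest, with means of 2.16 and 2.04. In BAT control 1 all 7 antigen presentation genes of MHC class II were highest, with a mean of 1.99. Processed pseudogenes numbered 384 in the BAT table, and 75.8% of them were highest in control 1, against 69.5% of protein-coding genes. In liver 67.0% of 109 processed pseudogenes and 54.5% of protein-coding genes were highest in control 8.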
